A study of Mus musculus with 4 samples.

How the data were processed

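Gene expression was measured on single-colour oligonucleotide arrays hybridised with biotin-labelled sense-strand cDNA, made from total RNA of SW620 cells, a cell line from a human colon carcinoma. The 4 arrays form 2 groups of 2, untreated cells and cells treated with F5446, as their titles state. The series calls them biological replicates without saying whether they came from separate cultures, so the p-values measure the spread between these arrays. The sample records give mouse as the organism, but the growth protocol names a human line and the platform annotation pairs the probe sets with human genes, so the data were treated as human.

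The deposited table holds 1 value per probe set and array, 53617 probe sets in all, which were taken as log2 signal. The table does not state its scale. The values run from 0.710 to 13.8, and the maximum lies above 11.09, the natural logarithm of the range of a 16-bit scanner, and under 16, its log2, so log2 was inferred. Partek is the one program named, per the submitters' processing notes; the background correction, normalization and probe set summary are not given in the sources used here. The array medians over all probe sets were 4.40, 4.41, 4.43 and 4.44, and whether the arrays were scaled to each other is not given in the sources used here. Such scaling would remove a difference in total RNA per cell. The table has no detection calls, so a fold change of a gene whose signal is low in 1 group may be smaller than the true one. For arrays, precision is limited by their number, 2 per group.

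A table of the platform's annotation names 16098 of the probe sets, each with 1 gene symbol and none with several; the other 37519 are unnamed here and entered only an alternative test. The named probe sets cover 14884 genes. Of these, 779 had more than 1 probe set, and the one with the highest mean over the 4 arrays represented the gene. In 320 such genes that passed the test, all probe sets changed with the same sign in 266. Many well-known genes, among them CDKN1A, FAS and the caspases, have no named probe set here and were not analysed. Genomic positions were not used here.

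The values as deposited were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, group as the only term, all 4 arrays). The p-values are two-sided and adjusted by Benjamini-Hochberg over the 14884 genes, with a threshold of 0.05. Errors of log2 fold changes are standard errors from this fit, and errors of group means are SDs over 2 arrays. For 4 genes both pairs of replicate arrays had identical values; none of them passed. Simulated arrays of 14884 genes had the real means and spreads drawn from genes of like mean. In them 100 genes were changed 2-fold (log2 of 1) and 100 by a log2 of 2. The fit recovered 54% and 88% of these, with 1 false call among 143. Far fewer genes changed there than the 40.9% that passed in the real data, so these rates need not carry over.

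Before the data were examined, 32 gene lists were fixed, along with the design, the rule for naming genes and the other settings to be tried. The replication-dependent histone and snoRNA lists had no named member and the olfactory receptor list had 1, which left 29 lists of at least 3 measured genes. Each was tested with limma's camera, which asks whether a list's genes moved relative to all other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 29 lists. In the simulation, 0 of 25 unchanged lists of 40 genes and the 1 changed list were called. The simulated genes varied independently, so this does not show how often camera would call an unchanged list of correlated genes. Camera was repeated with a correlation estimated for each list from these arrays, and limma's fry, which asks whether a list's genes moved on balance one way, was also run. With the estimated correlation 0 of the 29 lists passed, the smallest adjusted p being 0.11, and 4 had an unadjusted p under 0.05, while 14 passed with the preset one and 24 with fry. The list calls below are those of camera with the preset correlation. Of these 14, all but the list of genes with a ZNF symbol (fry adjusted p = 0.055) also passed with fry in the same direction. Fry does not compare a list with the other genes. A higher correlation does not account for every call lost. The estimate was 0.023 for the G1/S list but -0.0033 for the G2/M list, below the preset 0.01, and both calls were lost. With so few arrays, the test that uses the estimate has few residual degrees of freedom. For the G2/M list its unadjusted p was 0.0039, against 1.54e-36 with the preset correlation. Losses in that test therefore do not show which lists failed to move. Of the lists tested, 1 is not reported here, though it stays in the adjustment and in these counts.

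The genes named are SUV39H1 and SUV39H2; the 10 largest rises and 10 largest falls among genes past the threshold whose treated arrays both lay beyond both control arrays (long non-coding, microRNA and olfactory receptor genes left out); and, for each list, the 3 members past the threshold with the largest change, or the 2 with the smallest p where none passed. This gave 94 genes. Genes outside the rule are named as chosen after their values were seen.

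The alternatives were a replicate block, quantile normalization between arrays, centring each array on its median, leaving out dim genes (10344 kept), 2 other variance models, the mean of a gene's probe sets, all probe sets, 2 other thresholds and leaving out each array in turn. Centring used the median of the named genes on each array, 5.64 and 5.64 for control and 5.50 and 5.52 for F5446. It therefore moved every log2 fold change up by 0.13. The medians over all probe sets, in contrast, were slightly higher on the treated arrays, so the direction of the shift depends on this choice. Quantile normalization, run over all probe sets, moved the median log2 fold change by -0.03. Retests of 3 lists without the genes they share with the G1/S and G2/M lists were added after the data were seen.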

Results

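The arrays compared untreated SW620 cells with cells exposed for 2 days to 50 nM F5446, a small molecule described as a selective inhibitor of SUV39H1, the enzyme that places trimethyl marks on lysine 9 of histone H3. The series asks how SUV39H1 bears on apoptosis and the cell cycle in human colon carcinoma. Each group held 2 arrays, each with a log2 signal for 53617 probe sets, of which 14884 genes could be named. Across these genes the 2 control arrays correlated at r = 0.994 and the 2 treated arrays at r = 0.995, while pairs of 1 control and 1 treated array correlated at 0.943 to 0.945. These correlations are across genes, which are not independent replicates. The SD of the log2 difference between 2 arrays was 0.252 and 0.226 within the groups and 0.743 to 0.751 between them.

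F5446-treated cells had less mRNA of both SUV39H enzymes and differed from untreated cells at a large share of genes. SUV39H1 (probe set 17103413) fell 3.32-fold, from a log2 signal of 9.15 ± 0.038 to 7.42 ± 0.082 (SD, n = 2 each), a log2 fold change of -1.73 ± 0.08 (SE, adjusted p = 3.44e-07). Its second, dimmer probe set changed by -1.19 on the log2 scale. SUV39H2 (probe set 16702685), the related methyltransferase, fell 2.12-fold, from 7.81 ± 0.028 to 6.72 ± 0.051 (SD, n = 2 each; log2 fold change -1.08 ± 0.09, SE, adjusted p = 1.34e-05). In all, 6086 genes (40.9%) passed the test, 2714 higher and 3372 lower after F5446. A change of at least 2-fold was reached by 803 of the higher and 1090 of the lower genes, and one of at least 4-fold by 152 and 255. The treated arrays lay beyond both control arrays at 66.2% of genes, where chance gives 33.3%. With each array centred on the median of its named genes the split became 3420 higher and 2735 lower. Quantile normalization kept more falls, with 2546 higher and 3615 lower. Over all probe sets, named or not, 6274 were higher and 5483 lower. The balance of rises and falls thus depends on the scaling and on the probe sets tested.

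**Figure D1:**
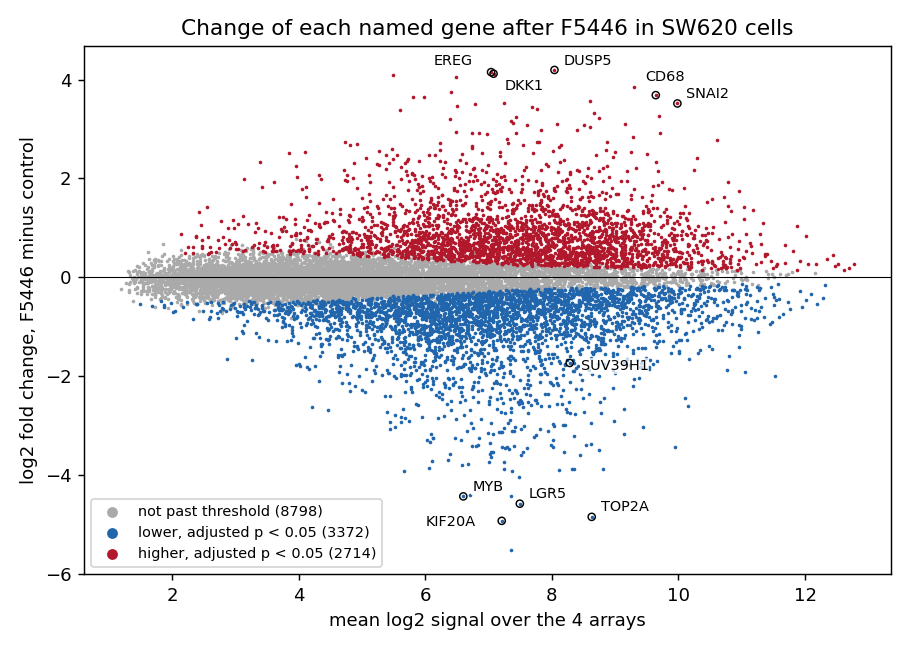
Log2 fold change (F5446 minus control, y axis) against the mean log2 signal over the 4 arrays (x axis); each point is 1 of 14884 named genes, coloured by whether it passed limma's test. The 3372 lower genes extend further from 0 than the 2714 higher genes, with KIF20A, TOP2A, LGR5 and MYB among the largest falls and DUSP5, EREG and DKK1 among the largest rises.

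Among the genes of largest change, DUSP5, a phosphatase that inactivates ERK, rose 18.3-fold, from 5.94 ± 0.27 to 10.1 ± 0.06 (SD, n = 2 each; log2 fold change 4.19 ± 0.12, SE); its second probe set changed by 1.44. EREG, which encodes the EGFR ligand epiregulin, rose 17.8-fold, DKK1, a secreted Wnt antagonist, 17.4-fold, and SCEL, which encodes the cornified-envelope protein sciellin, by a log2 fold change of 4.08. CDA, which encodes cytidine deaminase, rose 14.3-fold, the lysosomal glycoprotein gene CD68 12.9-fold, CREBRF 12.6-fold, the pseudogene ADAM20P1 12.5-fold, HIVEP2 11.8-fold and the kinase gene PIM1 11.5-fold. A second, dim probe set of HIVEP2 changed by -0.09. Among the largest falls, the mitotic kinesin gene KIF20A fell 30.4-fold, from 9.67 ± 0.14 to 4.75 ± 0.016 (SD, n = 2 each; log2 fold change -4.93 ± 0.10, SE), TOP2A, which encodes topoisomerase II alpha, 28.7-fold, the intestinal stem cell marker LGR5 23.9-fold, the transcription factor gene MYB 21.6-fold and HMMR 21.5-fold. GINS2, MME, GFRA3, OIP5 and CDKN3 fell between 15.1-fold and 21.1-fold. The adjusted p of these 20 genes in limma's test ran from 6.85e-09 (TOP2A and CD68) to 1.83e-06 (SCEL).

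Genes of DNA replication and mitosis fell almost without exception. Of 40 measured genes of the G1/S phase and DNA replication, 39 fell, 0 rose and 1 did not pass (39 fell adjusted over the list alone), with a median log2 fold change of -2.49. GINS2, a subunit of the replicative helicase complex, fell 21.1-fold, TYMS, which encodes thymidylate synthase, 14.7-fold and the replication factor MCM10 13.4-fold. Of 62 measured genes of G2/M and mitosis, 60 fell and 0 rose (61 fell adjusted over the list alone), with a median of -2.76 and KIF20A, TOP2A and HMMR in front. Both lists moved against the other genes, with camera adjusted p = 2.81e-25 for G1/S and 4.47e-35 for G2/M. With an estimated correlation the adjusted p was 0.17 and 0.11. Fry also called both down (adjusted p = 0.00089 and 0.00073). Another list, of CDK inhibitors, pocket proteins and D cyclins, did not move against the other genes. Of its 26 members only 12 were measured, of which 5 rose and 5 fell, over all genes and adjusted over the list alone. CDKN1A had no named probe set, so the list does not speak for CDK inhibitors as a class. CDKN3, a phosphatase that acts on cyclin-dependent kinases and is itself expressed in dividing cells, fell 15.1-fold, RBL1, which encodes the pocket protein p107, fell 6.10-fold, and CCNG2, which encodes cyclin G2, rose 2.79-fold. The list's median was 0.09, its mean -0.34 and its camera adjusted p = 0.80, while fry called it down (adjusted p = 0.0082).

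**Figure D2:**
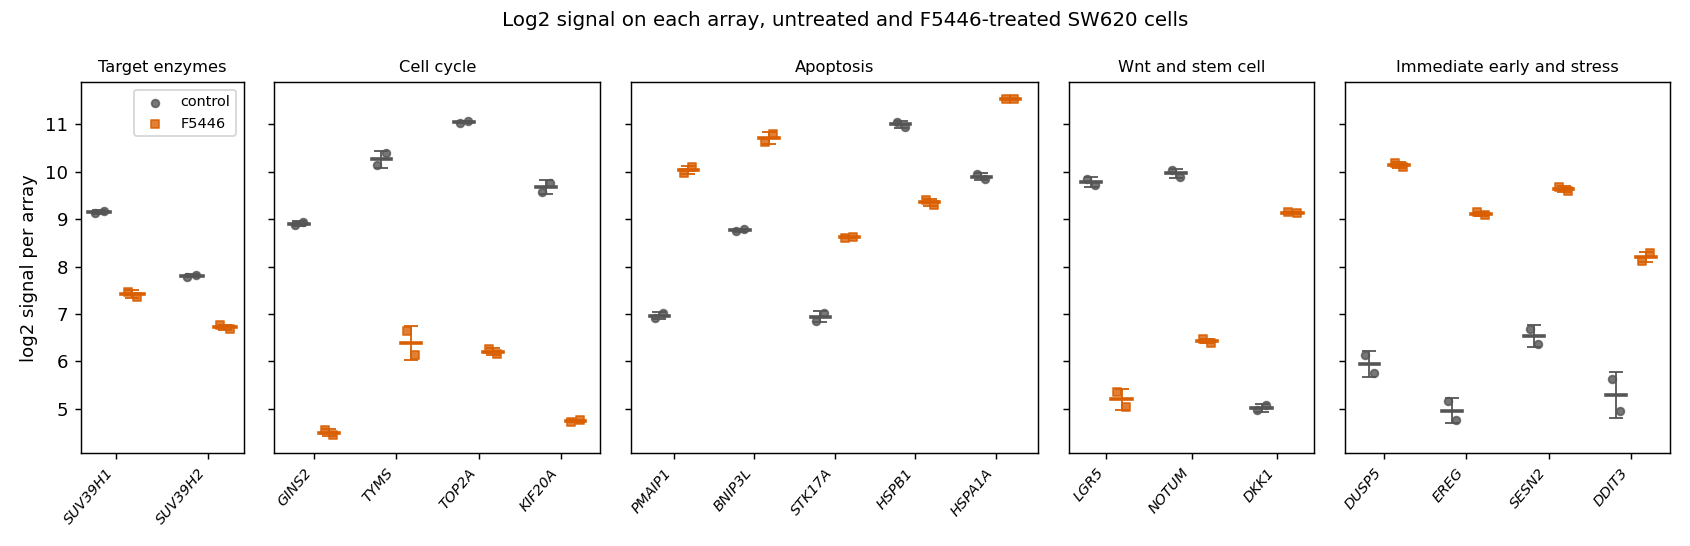
Log2 signal on each array (y axis) for 18 genes, grouped by function; circles are control arrays, squares F5446 arrays, bars the group mean and whiskers the SD (n = 2 each). All genes shown passed limma's test, and in every gene that passed the 2 treated arrays lay apart from the 2 control arrays. SUV39H1 fell from 9.15 to 7.42 and PMAIP1 rose from 6.97 to 10.0.

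Genes of apoptosis changed in both directions. Of 26 measured pro-apoptotic genes, 7 rose, 8 fell and 11 did not pass, with the same counts adjusted over the list alone. PMAIP1, which encodes the BH3-only protein NOXA, rose 8.43-fold, from 6.97 ± 0.079 to 10.0 ± 0.088 (SD, n = 2 each; log2 fold change 3.08 ± 0.08, SE, adjusted p = 2.40e-08). BNIP3L rose 3.83-fold and the kinase gene STK17A 3.19-fold. Among members chosen after their values were seen, BAX rose 1.66-fold, while APAF1, the scaffold of the apoptosome, fell 1.76-fold and HTRA2 fell 1.74-fold. As a group the list did not move against other genes (camera adjusted p = 0.71), and its median (-0.04, or 0.09 with each array centred) and mean (0.16) differed in sign. Of 21 measured anti-apoptotic genes, 9 rose and 4 fell (10 and 4 adjusted over the list alone), with a median of 0.18 and camera adjusted p = 0.054. The camera adjusted p was 0.039 after quantile normalization and 0.11 with dim genes left out, so the call depended on the setting. The small heat shock protein gene HSPB1 fell 3.13-fold. HSPA1A and HSPA1B rose 3.09-fold and 2.99-fold; these 2 HSP70 genes are near-identical in sequence, so their signals cannot be separated with certainty. MCL1, chosen after its value was seen, rose 1.92-fold.

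The expression of heterochromatin genes fell more often than it rose. Of 39 measured genes of H3K9 methylation and heterochromatin, 21 fell and 9 rose (22 and 9 adjusted over the list alone), with a median of -0.49 and camera adjusted p = 0.031, and adjusted p = 0.33 with an estimated correlation. LMNB1, which encodes lamin B1, fell 12.1-fold and UHRF1, which recruits DNA methyltransferase to replicating DNA, fell 7.93-fold. KDM7A, which encodes a demethylase of H3K9 and H3K27, rose 7.83-fold. UHRF1 is also on the G1/S list, and without it the list's adjusted p was 0.058, in a retest added after the data were seen. It was also 0.058 without control replicate 1, and ran from 0.018 to 0.067 over the camera alternatives with the preset correlation. DNA repair genes fell in 28 of 36 cases and rose in 1 (29 and 1 adjusted over the list alone; median -0.60, camera adjusted p = 1.32e-08, adjusted p = 0.19 with an estimated correlation). The uracil glycosylase UNG fell 5.88-fold, BRIP1 5.79-fold and XRCC2 5.75-fold. Genes with a ZNF symbol numbered 471, of which 126 rose and 71 fell, with the same counts adjusted over the list alone. Many zinc finger genes are packaged with H3K9 trimethylation, but these were taken by symbol alone. Which of them carry the mark in these cells was not measured. The median of the 471 was 0.08 (camera adjusted p = 0.025, adjusted p = 0.33 with an estimated correlation). ZNF185 rose 5.18-fold, ZNF699 3.86-fold and ZNF581 3.83-fold. Of 17 measured cancer-testis genes, which are normally silent outside the germ line, 1 rose (PIWIL1, 1.69-fold) and 1 fell (DAZL, 1.52-fold), while adjusted over the list alone 1 rose and 0 fell. Their camera adjusted p was 0.80, with a median of 0.02 (-0.01 after quantile normalization) and a mean of -0.0043. The log2 signal of DAZL (control 4.06 and 4.33, F5446 3.73 and 3.47) lay under 4.42, the limit of the dim-gene filter, on every array. That filter leaves DAZL out. PIWIL1 missed the threshold without F5446 replicate 2, at an adjusted p of 0.061. DAZL missed it without control replicate 2 (adjusted p = 0.15), F5446 replicate 1 (0.058) or F5446 replicate 2 (0.18), and with each array centred on its median (0.068).

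Most of the Wnt target and stem cell genes measured fell. Of 29 measured members, 21 fell and 4 rose, with the same counts adjusted over the list alone, at a median of -1.01 (camera adjusted p = 3.71e-05, adjusted p = 0.31 with an estimated correlation). LGR5 fell from 9.78 ± 0.099 to 5.21 ± 0.22 (SD, n = 2 each; log2 fold change -4.58 ± 0.12, SE). NOTUM, a secreted enzyme that inactivates Wnt ligands, fell 11.6-fold. DKK1 rose 17.4-fold and, chosen after their values were seen, CD44 rose 2.78-fold and MYC 2.28-fold. Of 32 measured genes of colonic differentiation, 4 rose and 6 fell over all genes and adjusted over the list alone (median -0.08, or 0.04 with each array centred, camera adjusted p = 0.86). VIL1, which encodes the brush-border protein villin, fell 14.7-fold, PLAC8 fell 3.22-fold and CEACAM5 rose 3.80-fold. Of 17 measured genes of the epithelial-mesenchymal transition, 9 rose and 4 fell, with the same counts adjusted over the list alone (median 0.48, camera adjusted p = 0.077). SNAI2, which encodes the repressor SLUG, rose 11.4-fold, ZEB1 4.37-fold, and THBS1, which encodes thrombospondin 1, fell 8.74-fold.

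Most of the immediate early genes and of the integrated stress response genes measured rose. Of 33 measured immediate early and growth factor feedback genes, 26 rose and 4 fell, with the same counts adjusted over the list alone (median 0.92, camera adjusted p = 1.75e-11, adjusted p = 0.31 with an estimated correlation). The EGFR ligand gene HBEGF rose 9.41-fold, behind DUSP5 and EREG. Of 27 measured genes of the integrated stress response and the unfolded protein response, 20 rose and 4 fell (22 and 4 adjusted over the list alone; median 0.75, camera adjusted p = 1.32e-08, adjusted p = 0.26 with an estimated correlation). The stress sensor gene SESN2 rose 8.57-fold, DDIT3, which encodes the transcription factor CHOP, rose 7.52-fold and ERN1, the endoplasmic reticulum stress sensor IRE1, 7.48-fold. NF-kB and inflammatory genes rose in 12 of 26 cases and fell in 3, with the same counts adjusted over the list alone (median 0.07, camera adjusted p = 0.025, adjusted p = 0.31 with an estimated correlation). The cytokine gene LIF rose 7.61-fold and the chemokine genes CXCL3 and CXCL8 3.78-fold and 3.42-fold. The interferon response list did not move against the other genes: 7 of 41 measured genes rose and 12 fell (7 and 13 adjusted over the list alone; median -0.14, camera adjusted p = 0.74). The RNA sensor IFIH1 fell 3.82-fold, while LAMP3 and ISG20 rose 2.62-fold and 2.57-fold. Of 10 measured antigen presentation genes, 2 rose and 4 fell (2 and 5 adjusted over the list alone; median -0.21, camera adjusted p = 0.28). MICB fell 1.87-fold, CALR 1.82-fold and MICA 1.52-fold.

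**Figure D3:**
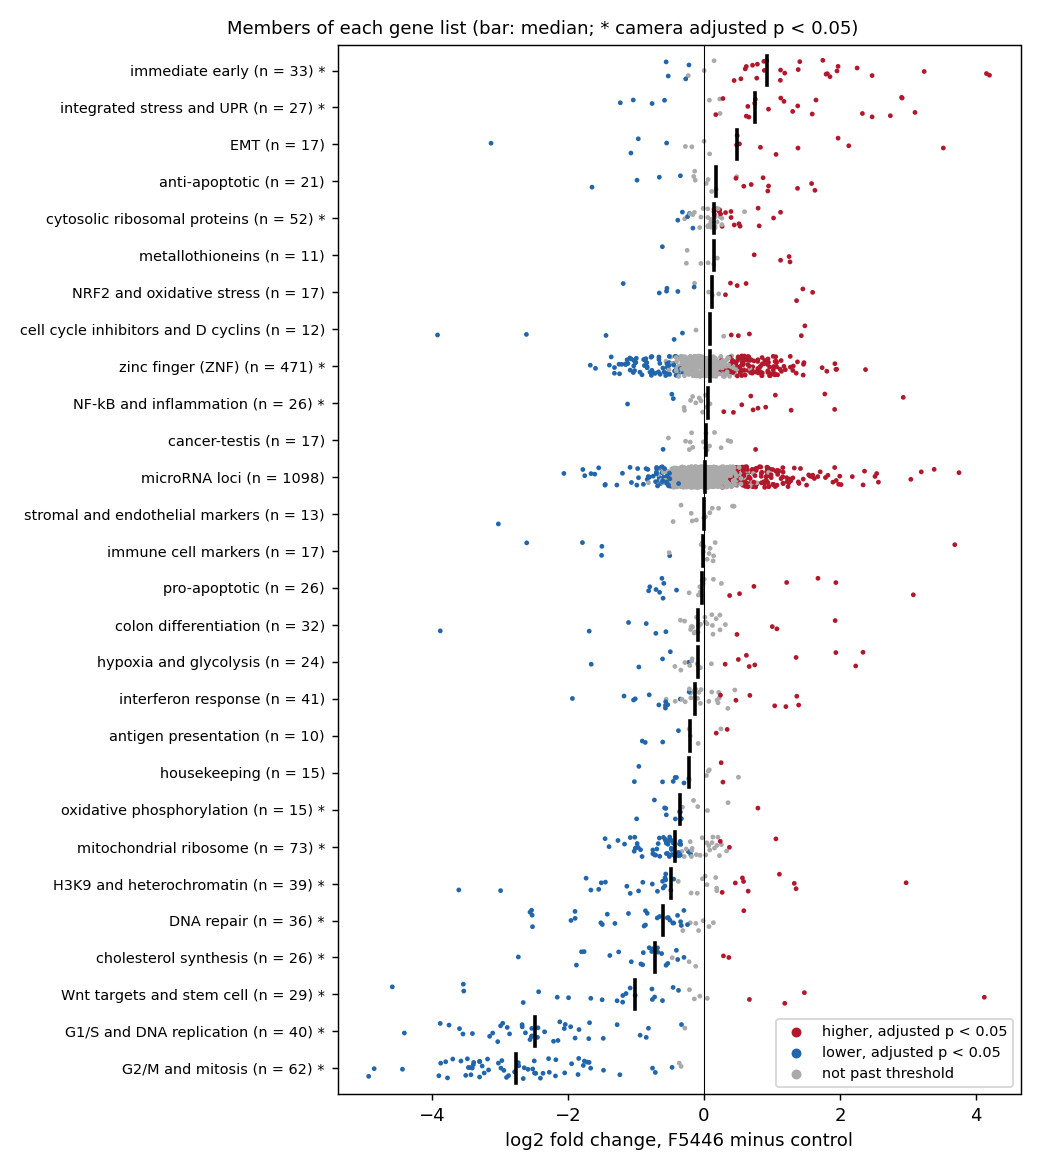
Log2 fold changes (F5446 minus control, x axis) of the measured members of 28 gene lists (y axis, with the number of members); each point is 1 gene, coloured by limma's test, the bar is the median, and an asterisk marks a camera adjusted p below 0.05 with the preset correlation. The 2 cell cycle lists lie furthest to the left, at medians of -2.49 and -2.76, and the immediate early list furthest to the right, at 0.92.

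Among metabolic and translation genes, cholesterol synthesis and the mitochondrial ribosome moved down and cytosolic ribosomal proteins slightly up. Of 26 measured genes of cholesterol and fatty acid synthesis, 21 fell and 2 rose (22 and 2 adjusted over the list alone; median -0.72, camera adjusted p = 5.91e-07, adjusted p = 0.20 with an estimated correlation). ACAT2, which makes acetoacetyl-CoA, fell 6.62-fold, DHCR7, which acts in the last steps of the pathway, 3.67-fold and PMVK 3.48-fold. Mitochondrial ribosomal protein genes fell in 48 of 73 cases and rose in 3 (50 and 5 adjusted over the list alone; median -0.43, camera adjusted p = 1.26e-06, adjusted p = 0.31 with an estimated correlation), with MRPL40 falling 2.74-fold, MRPS7 2.63-fold and MRPL13 2.40-fold. Of 15 measured respiratory chain genes 9 fell and 1 rose (10 and 2 adjusted over the list alone; median -0.35, camera adjusted p = 0.025, adjusted p = 0.31 with an estimated correlation); CYC1 fell 1.99-fold, UQCRC1 fell 1.66-fold and UQCRB rose 1.73-fold. This last call was lost when dim genes were left out (adjusted p = 0.060), without an intensity trend (0.067) and with the mean of a gene's probe sets (0.080), in a range of 0.022 to 0.080. Of 52 cytosolic ribosomal protein genes, 18 rose and 5 fell (19 and 5 adjusted over the list alone; median 0.15, camera adjusted p = 0.0026, adjusted p = 0.26 with an estimated correlation), led by RPL28 (2.18-fold), RPL37A (2.03-fold) and RPL22L1 (1.75-fold). With each array centred on its median, 31 rose and 1 fell.

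Hypoxia and glycolysis genes rose in 9 of 24 cases and fell in 5 (9 and 7 adjusted over the list alone; camera adjusted p = 0.47; median -0.09, or 0.04 with each array centred, mean 0.21). NDRG1 rose 5.05-fold and VEGFA 4.69-fold, beside BNIP3L. Of 17 genes of the oxidative stress response, 7 rose and 6 fell, with the same counts adjusted over the list alone (median 0.12, camera adjusted p = 0.47). NFE2L2, which encodes NRF2, rose 3.02-fold, OSGIN1 2.74-fold and SQSTM1 2.57-fold. Of 11 genes of metal homeostasis, 4 rose and 1 fell, with the same counts adjusted over the list alone (median 0.14, camera adjusted p = 0.091), with MTF1 rising 2.40-fold, MT1G 2.38-fold and MT1X 2.18-fold; the metallothionein genes are close in sequence and may share signal.

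Markers of other cell types did not move against the other genes in camera. Of 17 measured immune cell markers, 1 rose and 5 fell, with the same counts adjusted over the list alone (median -0.01, or 0.12 with each array centred, mean -0.24, camera adjusted p = 0.55, fry adjusted p = 0.027 downward). CD68 rose 12.9-fold, PRF1, which encodes perforin, fell 6.08-fold and LYZ, which encodes lysozyme, fell 3.45-fold. Of 13 stromal and endothelial markers, 1 passed in either count: LUM, which encodes lumican, fell 8.12-fold (list median -0.0012, or 0.13 with each array centred, camera adjusted p = 0.87). Housekeeping genes were not constant: 8 of 15 fell and 2 rose (9 and 2 adjusted over the list alone; median -0.22, camera adjusted p = 0.17), with VCP falling 2.03-fold, GPI 1.94-fold and PGK1 1.52-fold. Probe sets named for microRNA loci, which read precursor or host transcripts, numbered 1098, of which 137 rose and 59 fell (108 and 37 adjusted over the list alone; median 0.01, camera adjusted p = 0.084, or 0.045 without control replicate 1). With each array centred, 201 rose and 36 fell (median 0.14). MIR222 rose 13.4-fold, MIR29A 10.4-fold and the host transcript MIR22HG 9.14-fold. The single olfactory receptor gene measured, OR4C45, had a log2 fold change of -0.08 ± 0.16 (SE, adjusted p = 0.77).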

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

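Left-out arrays, the replicate block, both rescalings, the dim-gene filter, both variance models and the averaging of probe sets kept the 2 counts of changed genes within 1.5 times 2714 higher and 3372 lower. Without 1 array, which leaves 1 sample in its group and assumes that it varies like the other group, the counts ran from 2069 to 2431 higher and from 2580 to 2891 lower. The replicate block gave 2722 and 3342, with 96.9% of calls kept and no list call changed, and DAZL at an adjusted p of 0.055. With 2 arrays per group, the check of pairing gives a single correlation of deviations, 0.04, which does not establish that the numbers pair the arrays. Of the calls, 96.9% kept call and direction under quantile normalization and 89.5% under centring, and 0 turned direction. Testing all 53617 probe sets (control probe sets could not be told from others) gave 6274 higher and 5483 lower. Why the balance turned was not tested. Adjusted p under 0.05 with at least 2-fold gave 803 and 1090, and unadjusted p under 0.05 with at least 1.5-fold gave 1703 and 2248; these thresholds are stricter in fold by construction. SUV39H1 ran from -1.80 to -1.46 and SUV39H2 from -1.12 to -0.96 on the log2 scale, past the threshold in each alternative. Of the list tests, the G1/S and G2/M calls were lost in camera with an estimated correlation (adjusted p = 0.17 and 0.11). With 2 arrays per group this correlation, and the test that uses it, rest on 2 residual degrees of freedom. Under fry the CDK inhibitor list passed in the downward direction (adjusted p = 0.0082), opposite to camera, and the pro-apoptotic list passed upward (0.020). The anti-apoptotic list, at 0.054, passed under quantile normalization (0.039), the mean of probe sets (0.038) and fry (0.015), and ran from 0.036 to 0.091 without 1 array, passing without control replicate 2 or F5446 replicate 1. Over all lists and alternatives, 311 results kept their call, 22 lost it, 17 gained it and 1 passed in the opposite direction, lists past the threshold in neither setting counting as kept whatever their sign; the cause was not tested. Fry also called the antigen presentation (0.025), colonic differentiation (0.013), immune marker (0.027) and housekeeping (0.0035) lists down and the hypoxia (0.024), oxidative stress (0.0063), metal homeostasis (0.023) and epithelial-mesenchymal (0.023) lists up. Besides the losses with an estimated correlation, the heterochromatin list missed the threshold without control replicate 1 (0.058), the heterochromatin and respiratory chain lists both did without dim genes (0.060) and without an intensity trend (0.067), the respiratory chain list did with the mean of probe sets (0.080) and the ZNF list did under fry (0.055). The microRNA list passed after quantile normalization (0.039), without dim genes (0.0076) and without control replicate 1 (0.045). Without the cell cycle genes, a test chosen after the data were seen, the DNA repair and Wnt lists still passed (1.52e-07 and 0.00011) and the heterochromatin list did not (0.058). Of the named genes, 6 results in PIWIL1 and DAZL were lost, and OR4C45, near 0 throughout, turned to 0.046 under centring and ran from -0.16 to 0.0031 without 1 array. The pseudocount alternative was not run, since the table is already on a log scale, and camera has no robust variance setting. The absence of detection calls limits what can be said of genes with low signal.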

Other observations

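The symbol families, the test of the G2/M list against matched lists and the ranking of SUV39H1 were chosen after the results were seen. Genes sharing a symbol root were tested with camera as 224 families of at least 8 genes. With the preset correlation 13 passed, 7 up and 6 down. With an estimated one 0 passed (adjusted p = 0.98 for each of the 13), and 2 of the 224 had an unadjusted p under 0.05. That test rests on 2 residual degrees of freedom, so after adjustment over 224 families it could call little. Its outcome does not tell the families apart. Intraflagellar transport genes (IFT), which build cilia, fell in 13 of 17 cases and rose in 1 (median log2 fold change -1.01, adjusted p = 0.00043), with IFT81 falling 6.57-fold and IFT80 4.29-fold. Kruppel-like factor genes (KLF) rose in 10 of 18 cases and fell in 0 (median 0.73, adjusted p = 0.0011), with KLF9 rising 4.18-fold and KLF6 3.47-fold. Dual-specificity phosphatase genes (DUSP) rose in 13 of 24 cases and fell in 1 (adjusted p = 0.0046); DUSP10 rose 11.1-fold and DUSP16 3.73-fold. Suppressors of cytokine signalling (SOCS) rose in 6 of 8 cases and autophagy genes (ATG) in 8 of 13 (adjusted p = 0.011 and 0.012), with SOCS3 at 2.75-fold and ATG12 at 4.27-fold. Tetraspanin genes (TSPAN) fell in 11 of 22 cases and NUDT genes in 14 of 24 (adjusted p = 0.039 and 0.040), and each family named here kept the sign of its median under both rescalings. KLF6 and several DUSP genes are also on the immediate early list.

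Outside the rule for naming genes, the largest fall of all named genes was in the antisense transcript JAKMIP2-AS1, at 45.9-fold, and among long non-coding RNAs LINC00622 rose 16.5-fold. MIR221, the neighbour of MIR222 in 1 microRNA cluster, rose 8.22-fold. Among the 37519 unnamed probe sets, 3990 were higher and 2634 lower when all probe sets were tested together.

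The breadth of the change, 6086 genes with 2 arrays per group, was weighed first. The tables argue against a scale difference left between the deposited arrays as the whole cause. Of the called genes, 89.53% kept call and direction under centring and 96.9% under quantile normalization, each above the 80% set before these values were seen. Whether the arrays were scaled before deposit is not given, and quantile normalization moved the median log2 fold change by only -0.03. Neither rescaling can therefore show what an earlier scaling did to the values. Of the 3 splits of the arrays into 2 and 2, 1, the real one, called 6086 genes in limma's test and the others at most 0 (171 at an unadjusted p under 0.05), and 3 splits are too few for a share under 0.05. The median of the G2/M genes, -2.76, lay below those of all 10000 random lists matched on mean expression, which ran from -0.53 to 0.43. A labelling or hybridization batch that acts on genes by their signal alone would move such lists alike. It would not by itself give that fall. The list was already known to have the lowest median, so the comparison largely restates the fall. A batch or culture difference that acts on genes in another way cannot be told from the treatment with these arrays. The labels give no batch to enter in the fit, and no other dose or time was analysed here.

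SUV39H1 mRNA fell along with the replication genes, and a candidate explanation is that it fell as a gene expressed in dividing cells. Its log2 fold change of -1.73 lay inside the range of the G1/S list (-4.40 to -0.28), and 77.5% of that list fell as far or farther. Of 500 genes of like mean expression, 5% fell as far or farther, and their central 95% (-2.36 to 1.76) still held it, so the explanation stays open by the bound set, and an effect of the inhibitor on its own target's transcript stays open as well.

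Loss of a repressive mark could release silent genes, which would make rises outnumber falls among dim genes. Among the 4962 genes of lowest mean signal, 35.61% of called genes were higher (exact 95% binomial interval 31.05% to 40.38%, counting error only, genes not being independent), and 32.82% after quantile normalization. These shares met the bounds against release and against scaling written before they were seen. Quantile normalization did not turn the share, but it changed these arrays little (a median shift of -0.03). Whether they were already scaled to each other is not given, so this outcome does not decide on low-signal scaling. Release is nevertheless left open, because an upward shift common to all genes is not excluded and would turn the share. Centring on the medians of the named genes, which adds the same 0.13 to every log2 fold change, gave 62.64% (57.97% to 67.14%). The medians over all probe sets were slightly higher on the treated arrays and call for no such upward shift. Release of single genes is open as well: at 2-fold or more 44 of these genes were higher and 49 lower, at 4-fold or more 6 and 3, and a gene that rose or fell strongly can leave this group.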
